A study of Mus musculus with 7 samples.

How the data were processed

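Cells of dissected outflow tracts from mouse embryos at E10.5 were profiled by single-cell RNA sequencing. There is 1 wild-type library and 1 library for each of 6 homozygous knockouts on C57BL/6J, made with CRISPR/Cas9. Per the labels' protocols, tissue was digested at 37 °C for about 15 min, passed through a 40 µm strainer and made into libraries with a MobiDrop 3' kit, while a label field names 10x Genomics. The submitters' processing notes name Cell Ranger 6.1.1, Seurat 4.1.3 and the builds GRCm38 and mm10 without stating what each was used for. The aligner's settings, the rule that called cells and the number of embryos per library are not given in the sources used here. The deposited matrices hold raw UMI counts for 54232 genes per barcode, whole numbers without normalization, and the lowest barcode total is 500 counts in each library. Gene identifiers were matched to GENCODE release M21 (54079 found, 53072 with the same symbol).

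Total counts per library were 128536554 (wild type), 117971657 (Agbl2 knockout), 126714949 (Mlf1), 145919864 (Pkhd1l1), 147166376 (Ppef2), 118593630 (Sptbn5) and 124995051 (Tekt3). Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were used. Doublet scores came from Scrublet in scanpy 1.11.5. Its automatic threshold called 0 to 2 cells per library, so the planned rate of 0.4% per 1000 cells was used and the cells with the highest scores were left out. Cells of the 7 libraries were clustered together without batch correction: counts scaled to 10000 per cell and logged, 2000 variable genes, 40 principal components, 15 neighbours and Leiden clusters at resolution 1 (leidenalg 0.10.2). Sex-linked, haemoglobin, mitochondrial and ribosomal genes were kept out of the variable genes. A cluster was named by its best marker score if this was at least 0.8, led the next by 0.3 and rested on at least 3 markers, and if at most 30% of its cells had been called doublets. A cluster stayed unnamed if its cells' median UMIs were under 0.333 of their own library's and no marker of the name was among its top 10 genes. Cardiomyocyte cluster 9, without a marker among these, lay just above this limit (0.366) and was named by 5 markers. These naming thresholds were set after the data were seen, and the marker genes before. The 4 named classes with the most cells and at least 100 cells in each library were compared.

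Counts were summed per library and class. The wild-type library was compared with the 6 knockout libraries with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, 5 residual degrees of freedom, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The lone wild-type library is assumed to vary like the knockouts. DESeq2 1.42.0 was run beside it. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and with a correlation estimated per list and with fry. 37 lists were written before the data were examined, and mitochondrially encoded and haemoglobin genes were taken by name.

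For each knockout, the log2 ratio of TMM-scaled CPM to the wild-type library was taken with an exact counting interval, beside whether the library lay outside the range of the other 6. Shares of cells have exact binomial 95% intervals. A gene list is given as the median log2 ratio of members with a mean of at least 5 CPM, set against 10000 random lists of the same size and expression. Lists are described where their median had the same sign and lay above the 99.5th or below the 0.5th percentile in at least 3 of 4 classes, a rule set after the data were seen. Hedgehog targets are given for every knockout. Named genes follow a rule written before the data were examined: up to 3 higher and 3 lower per knockout and class among genes with at least 100 counts and 20 CPM in the higher library, an interval excluding no difference and a level outside the other 6 libraries, ranked by the gap to the nearest of these. The rule leaves out Xist, Y-linked, haemoglobin, mitochondrial and ribosomal protein genes and unnamed gene models. In described lists the members farthest from the wild type are named. The samples, the comparisons, the tests, the gene lists and all alternatives not said to be added later were also fixed before the data were examined.

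The ratio and list calculations were tested on simulated Poisson counts from a common profile, without spread between libraries or correlation between genes. This checks the calculation only. The counting intervals covered the true ratio for 94.9% to 95.7% of genes, and random lists fell outside the 2.5th to 97.5th percentile in 2.0% to 7.50% of draws. In simulated counts for the wild type against 6 knockouts, between 1 and 9 unchanged genes were called per class. The alternatives tried were RLE size factors, DESeq2, no expression filter, a stricter cell filter (1500 genes, 5% mitochondrial), no doublet removal, doublets at 0.8% per 1000 cells, Leiden resolution 2, a class per cell by its highest marker score, shares without erythroid cells, sums without haemoglobin and mitochondrial genes, leaving out each knockout library, the libraries of the wild type's date only, CPM without TMM and members with at least 20 CPM. Cells of unnamed clusters were not used in the comparisons of expression. File dates were read as batches of 3, 2, 1 and 1 libraries, listed below. For the Ppef2 and Pkhd1l1 knockouts, each alone on its date, date and genotype cannot be told apart. What the Agbl2 and Tekt3 knockouts share against the wild type may likewise come from their date. Correlations, doublet scores and figures used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 under Python 3.11.15.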

Results

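The outflow tract is the vessel through which blood leaves the embryonic heart, and its division into aorta and pulmonary trunk goes wrong in tetralogy of Fallot, the heart defect that the series title links to ciliary genes. Single-cell RNA sequencing of dissected mouse outflow tracts at E10.5, about midway through gestation, gave 7 libraries, 1 per genotype. They come from wild-type embryos and from embryos homozygous for a knockout of Agbl2, Mlf1, Pkhd1l1, Ppef2, Sptbn5 or Tekt3 on the C57BL/6J background, and the number of embryos per library is not given. The series speaks of littermates of each strain, but which litter the 1 wild-type library came from is not stated. The libraries held between 117971657 counts (Agbl2 knockout) and 147166376 counts (Ppef2 knockout) of unique molecular identifiers (UMIs), from 7832 to 17493 barcodes. After filtering, 6693 to 15402 cells per library were kept, with a median of 6460 to 13883 UMIs per cell. File dates place the wild type with the Mlf1 and Sptbn5 knockouts, the Agbl2 and Tekt3 knockouts together, and the Ppef2 and Pkhd1l1 knockouts on dates of their own. The ratios of the Mlf1 and Sptbn5 knockouts to the wild type are thus taken within 1 date, and those of the other 4 knockouts across dates. With 1 library per genotype, each knockout can be described against the wild-type library but not tested against it. The 95% intervals given in parentheses after levels, shares and log2 ratios cover counting error only.

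The 6 targeted genes differ in where they act. Agbl2 encodes a carboxypeptidase that removes glutamates from tubulin, Tekt3 a filament protein of ciliary microtubules, Sptbn5 a spectrin, Ppef2 a calcium-binding phosphatase, Pkhd1l1 a large receptor-like membrane protein and Mlf1 an adaptor protein. In GRCm38 their loci are Agbl2 (ENSMUSG00000040812, chromosome 2, 90782727 to 90834437), Sptbn5 (ENSMUSG00000074899, chromosome 2, 120041493 to 120085693), Mlf1 (ENSMUSG00000048416, chromosome 3, 67374097 to 67400003), Ppef2 (ENSMUSG00000029410, chromosome 5, 92226679 to 92256278), Tekt3 (ENSMUSG00000042189, chromosome 11, 63061654 to 63094964) and Pkhd1l1 (ENSMUSG00000038725, chromosome 15, 44457494 to 44601369). Over all cells, Agbl2 stood at 1.48 (1.27 to 1.73) CPM (counts scaled to a common library total) in its own knockout and 3.15 (2.83 to 3.48) in the wild type, with 1.85 to 2.99 in the other 5 knockouts. Pkhd1l1 stood at 4.38 (4.04 to 4.75) CPM in its knockout and 12.9 (12.2 to 13.5) in the wild type, but the epicardial cells that express it most were fewer there. Within them it stood at 93.0 (84.7 to 102) against 121 (114 to 129) CPM, with 55.6 to 112 in the other 5 knockouts. Over all cells the other 5 ranged from 1.22 to 10.3 CPM. Mlf1 was at 26.5 (25.6 to 27.4) CPM in its knockout and 23.0 (22.2 to 23.9) in the wild type, with 12.7 to 26.2 elsewhere. Sptbn5 was at 0.604 (0.468 to 0.767) against 0.814 (0.659 to 0.994) CPM (others 0.139 to 0.630) and Ppef2 at 0.315 (0.228 to 0.425) against 0.365 (0.264 to 0.491) CPM (others 0.187 to 0.315). Tekt3 was near the limit of detection, at 0.125 (0.0681 to 0.209) CPM in its knockout and 0.0509 (0.0187 to 0.111) in the wild type (others 0.00829 to 0.0729). Since 3' tags can lie outside a deleted segment, a level that is kept says nothing about the genotype.

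Cardiomyocytes, endocardial and endothelial cells, the mesenchyme of the endocardial cushions and neural crest mesenchyme make up the outflow tract wall, and cells resembling each were found by their marker genes in every library. The class names stand for such likeness. Cardiomyocytes were the most numerous named class in each of the 7 libraries, at 28.8% (28.1 to 29.6) of the wild-type cells, 50.9% (49.7 to 52.1) in the Agbl2 knockout, 44.5% (43.3 to 45.7) in the Mlf1 knockout, 34.5% (33.5 to 35.6) in the Sptbn5 knockout, 27.1% (26.2 to 28.1) in the Pkhd1l1 knockout, 21.5% (20.7 to 22.2) in the Ppef2 knockout and 21.5% (20.9 to 22.2) in the Tekt3 knockout. Cushion mesenchyme, which forms the septum and valves, made up 16.7% (16.1 to 17.4) of wild-type cells and was scarcer in the Agbl2 (3.97%), Mlf1 (6.25%), Ppef2 (7.10%) and Pkhd1l1 (12.1%) knockouts, against 18.4% in the Sptbn5 and 19% in the Tekt3 knockout. Endothelial cells varied least, from 10.51% (Sptbn5 knockout) to 13.9% (Agbl2 knockout), with 12.1% in the wild type. Neural crest mesenchyme was 3.70% (3.39 to 4.03) of wild-type cells, 11.4% (10.6 to 12.2) in the Agbl2 knockout and 8.23% in the Pkhd1l1 knockout, and lay between 3.48% and 6.87% in the others. Epicardial cells were fewest in the Agbl2 knockout, at 0.553% against 5.23%, and erythroid cells were most frequent in the Ppef2 knockout, at 4.27% against 1.42%. Cells of clusters that met no naming rule made up 29.9% of the wild-type library, 15.1% of the Agbl2, 23.7% of the Mlf1, 35.4% of the Pkhd1l1, 38.8% of the Ppef2, 25.3% of the Sptbn5 and 33.7% of the Tekt3 knockout library.

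**Figure D1:**
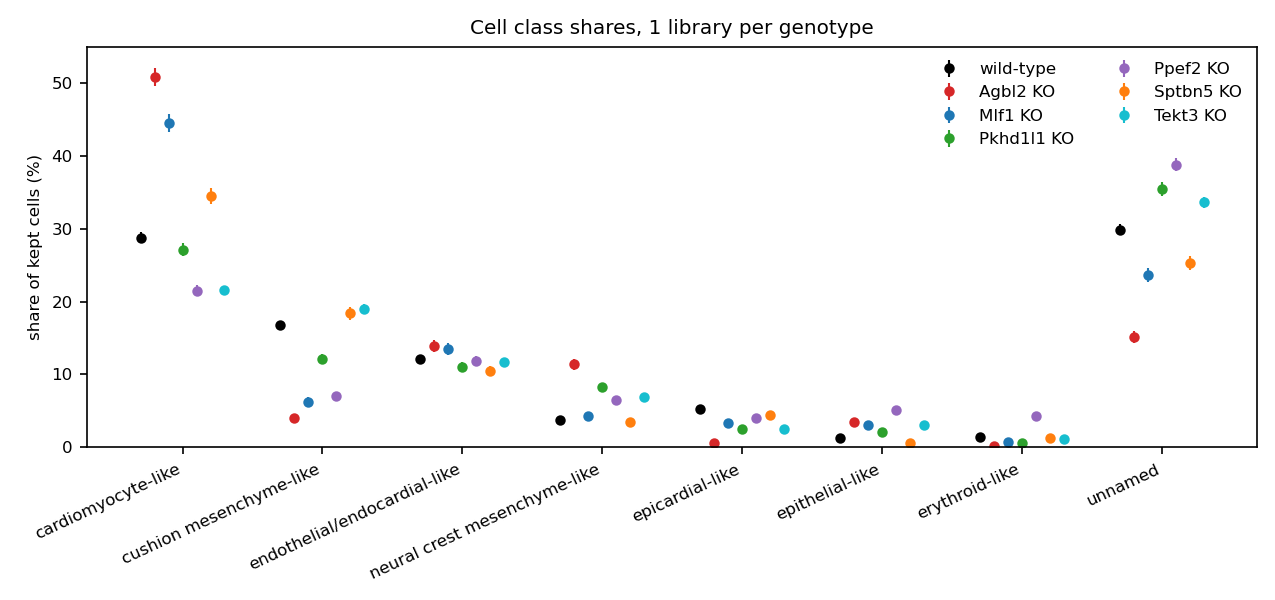
Share of kept cells in percent for each cell class and library, with exact binomial 95% intervals from counting error only. The Agbl2 knockout had 50.9% cardiomyocytes against 28.8% in the wild type and 3.97% cushion mesenchyme against 16.7%.

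Several of these differences depended on how cells were assigned. The surplus of cardiomyocytes in the Agbl2 knockout was 22.1 percentage points, 13.5 with a stricter cell filter, 5.92 when each cell took the class of its highest marker score and 2.36 with finer clusters. The Sptbn5 knockout's cardiomyocyte difference of 5.71 points became -3.08 by marker score, and the Tekt3 knockout's cushion difference of 2.31 became -1.51 with finer clusters and -1.65 by marker score. The deficit of cushion mesenchyme in the Agbl2, Mlf1, Pkhd1l1 and Ppef2 knockouts and the surplus of neural crest mesenchyme in the Agbl2, Pkhd1l1, Ppef2 and Tekt3 knockouts kept their direction under each alternative tried.

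Whether loss of any ciliary gene leaves a shared mark was asked by setting the wild-type library against the 6 knockouts taken as replicates. Cytosolic ribosomal protein genes, which supply the ribosome, were lower as a group in the wild type in all 4 classes, and sarcomere genes were higher by their median in wild-type cushion and neural crest mesenchyme, cell types that do not build sarcomeres, though their summed level was not above every knockout. Targets of BMP signalling, the pathway that drives cushion formation and outflow septation, were lower in wild-type cardiomyocytes. These group differences passed only with a preset correlation between genes. No single gene, Hedgehog pathway targets included, passed in any class. As for the sarcomere genes, no free RNA was taken off. By member, their level in neural crest mesenchyme was 0.724 to 1.29 times the endothelial one over the libraries (median of 18 members). Cardiomyocytes held 27.4 to 91.2 times the endothelial level. Free cardiomyocyte RNA thus stays open as a source, here and in the single knockouts below.

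edgeR called 0 genes in each class at an adjusted p under 0.05, and 0 with p adjusted within each list. At an unadjusted p under 0.05 it counted 159 of 18430 genes in cardiomyocytes, 137 of 17698 in cushion mesenchyme, 104 of 17563 in endothelial cells and 109 of 15338 in neural crest mesenchyme. DESeq2 also called 0 in each class, with 170, 120, 78 and 72 genes at an unadjusted p under 0.05. On simulated counts with a dispersion of 0.1, edgeR found 3 to 4 of 100 genes changed by a log2 fold of 1. It found 47 to 60 of 100 changed by 2. Moderate shared changes would mostly be missed. The real fit may miss more, since its share of genes under 0.05 was below the 0.05 that chance gives.

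Among gene lists, limma's camera with a preset correlation called 10 in cardiomyocytes, 8 in cushion mesenchyme, 5 in endothelial cells and 5 in neural crest mesenchyme, and none of these calls held with an estimated correlation, where the lowest adjusted p per class were 0.594, 0.765, 0.963 and 0.860. With each knockout library left out in turn, which was added after the data were seen, the counts ran from 11 to 17, 7 to 10, 4 to 8 and 5 to 9. There were 17 in cardiomyocytes and 8 in neural crest mesenchyme without the Pkhd1l1 knockout. There were 8 in endothelial cells and 9 in neural crest mesenchyme without the Sptbn5 knockout. The tallies of knockouts above or below wild type that follow share the 1 wild-type library, so they are not separate support. Ribosomal protein genes had median log2 fold changes (wild type over knockouts) of -0.18, -0.23, -0.22 and -0.35 in the same order of classes, with adjusted p = 2.94e-25 in neural crest mesenchyme and 0.860 with an estimated correlation, and the median was above wild type in 5 of 6, 6 of 6, 5 of 6 and 6 of 6 knockouts. Sarcomere genes had medians of 0.47 in cushion mesenchyme (adjusted p = 7.01e-07, and 0.765 with an estimated correlation) and 0.58 in neural crest mesenchyme (adjusted p = 5.67e-09, and 0.860), with the median below wild type in 6 of 6 and 6 of 6 knockouts. The summed level of the list, in which Tpm1 and Actc1 weigh most, was 2834 CPM in wild-type cushion mesenchyme but 2899.7 in the Sptbn5 and 2909 in the Tekt3 knockout. In neural crest mesenchyme it was 2385 CPM in the wild type and 2731 in the Agbl2 knockout. BMP targets had medians of -0.48 in cardiomyocytes (adjusted p = 1.32e-06, and 0.594 with an estimated correlation) and -0.33 in neural crest mesenchyme (adjusted p = 0.0334, and 0.860), with the list above wild type in 5 of 6 and 4 of 6 knockouts. The neural crest call ended without the Agbl2 knockout (adjusted p = 0.284) and without the Tekt3 knockout (0.0988). Notch pathway genes (-0.51, adjusted p = 7.39e-04, above wild type in 6 of 6 knockouts) and collagens and matrix (-0.33, adjusted p = 0.00448, 5 of 6) were lower in wild-type cardiomyocytes, where genes of tubulin glutamylation and tyrosination were higher (0.15, adjusted p = 0.0395, below wild type in 4 of 6 knockouts). This last call ended without the Agbl2 knockout (adjusted p = 0.0549). In wild-type cushion mesenchyme the targeted genes and their paralogues were higher (0.40, adjusted p = 0.0352, below wild type in 5 of 6 knockouts). This ended without the Agbl2 (adjusted p = 0.0611) and without the Sptbn5 knockout (0.0564). The other calls named here passed with each knockout library left out, at an adjusted p of 0.0354 or less. With the date code as a block, also added after the data were seen, 7, 8, 3 and 6 lists were called. Of the calls named here, the Notch call, both sarcomere calls and the ribosomal ones outside endothelial cells remained, while ribosomal genes in endothelial cells were at an adjusted p of 0.163. BMP targets were at 0.262 in cardiomyocytes and 0.586 in neural crest mesenchyme, collagens and matrix at 0.0675, tubulin glutamylation at 0.0675 and the targeted genes and paralogues at 0.365.

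Hedgehog signalling is read out through the primary cilium, so its target genes were described for each knockout. camera did not call the targets in any class, with adjusted p = 0.0880 in cardiomyocytes, 0.532 in cushion mesenchyme, 0.533 in endothelial cells and 0.440 in neural crest mesenchyme. The pathway's components were higher in wild-type neural crest mesenchyme by limma's fry (adjusted p = 0.0359) but not by camera (0.0651, and 0.860 with an estimated correlation), with a median of 0.24 and the list below wild type in 6 of 6 knockouts. Without the Agbl2 knockout library camera called them as well (0.0317). Ptch1, the receptor gene that Hedgehog signalling induces, had log2 ratios to wild type in cushion mesenchyme of -0.02 in the Agbl2, -0.14 in the Mlf1, -0.22 in the Pkhd1l1, 0.16 in the Ppef2, -0.24 in the Sptbn5 and 0.39 in the Tekt3 knockout. The cyclin gene Ccnd1 was lower in the Agbl2 knockout in all 4 classes, from -1.73 (-1.83 to -1.63) in cardiomyocytes to -0.47 (-0.53 to -0.41) in cushion mesenchyme, while Mycn was lower in its cardiomyocytes (-0.47) and higher in its neural crest mesenchyme (1.45, 1.24 to 1.67). Gli1, the transcriptional effector, was detected in neural crest mesenchyme, where it was lower in the Agbl2 knockout (-1.15, -1.47 to -0.83) and higher in the Sptbn5 knockout (0.45, 0.11 to 0.80). Medians of the target list in cardiomyocytes, cushion mesenchyme, endothelial cells and neural crest mesenchyme were -0.47, -0.02, -0.44 and -0.59 in the Agbl2 knockout and -0.27, 0.39, 0.07 and -0.17 in the Tekt3 knockout. The corresponding medians were -0.04, -0.01, 0.02 and -0.20 in the Mlf1, -0.25, -0.18, -0.33 and -0.15 in the Pkhd1l1, -0.12, 0.16, -0.23 and -0.41 in the Ppef2, and -0.03, -0.11, -0.20 and 0.20 in the Sptbn5 knockout. The list had 3 detected members in cardiomyocytes and cushion mesenchyme, 4 in endothelial cells and 9 in neural crest mesenchyme.

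No list of genes of the cilium itself met the rule for a described list in any knockout. Over the 6 knockouts and 4 classes, list medians ran from -0.09 to 0.17 for intraflagellar transport, which carries cargo along the cilium, -0.07 to 0.32 for the BBSome and its chaperones, -0.19 to 0.21 for the transition zone at the ciliary base and -0.21 to 0.13 for centriole and basal body genes. The lowest of the last, in cardiomyocytes of the Pkhd1l1 knockout, had 2 of 19 members higher. Genes of tubulin glutamylation and tyrosination ran from -0.35 to 0.15, lowest in cardiomyocytes of the Agbl2 knockout, where 4 of 12 were higher. Motile cilia genes were too few above the detection limit for a median. In cushion mesenchyme of the Agbl2 knockout, the transition zone (0.21) and intraflagellar transport (0.12) stood above the other knockouts.

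In the Agbl2 knockout library, genes that cells switch on when oxygen is short stood far above every other library. Egln3, an oxygen-sensing hydroxylase, Vegfa, the growth factor for vessels, and Bnip3, which directs mitochondria to degradation, were higher than in the wild type in all 4 classes, together with glucose transporters and the glycolytic enzymes. Genes of the unfolded protein and integrated stress response were higher in 3 classes. Haemoglobin transcripts and mitochondrially encoded transcripts were lower in all 4 classes, and genes of cholesterol synthesis were lower in 3. This library also held few erythroid cells.

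All 20 detected members of the glycolysis and hypoxia list were higher in each class, with median log2 ratios to wild type of 1.31 in cardiomyocytes, 1.09 in cushion mesenchyme, 2.06 in endothelial cells and 3.02 in neural crest mesenchyme, each above the 99.5th percentile of expression-matched random lists. Egln3 (4.78, 4.58 to 4.99) and Ndrg1 (4.13, 3.89 to 4.38) led in cardiomyocytes, Vegfa (3.58, 3.29 to 3.89) and Egln3 (3.30, 2.97 to 3.63) in cushion mesenchyme, Bnip3 (5.13, 4.92 to 5.34) and Ankrd37 (4.32, 4.03 to 4.63) in endothelial cells, and Ndrg1 (5.40, 4.03 to 7.28) and Egln3 (4.58, 4.00 to 5.24) in neural crest mesenchyme. Part of the difference went with clusters made up almost wholly of this library's cells, since 95.4% of its neural crest mesenchyme lay in cluster 31 (cluster 10 in every other library) and 40.7% of its cardiomyocytes in cluster 6, against cluster 0 in the wild type. Its largest endothelial cluster was cluster 25, with 36.6% of these cells and 12.7% of the wild-type ones, whose largest was cluster 20. Cells of clusters 6 and 25 were shallow, with medians of 0.184 and 0.165 times the median UMIs of their own library. Cells of cardiomyocyte cluster 30 were deep, at 2.10 times. Before doublet removal, 1051 of its 1055 cells came from this library, and Vegfa and Egln3 were among its top 10 genes. In an analysis added after the data were seen, the median within cardiomyocyte clusters shared by the libraries was 0.57 (cluster 0), 0.41 (cluster 12) and 0.34 (cluster 13), and within endothelial cluster 20 it was 1.84. Within endothelial cluster 3 it did not count as moved from the class value. Glycolysis and hypoxia genes were not kept out of the clustering, and Vegfa is a top gene of clusters 6 and 30. Cells low in these genes may have stayed in the shared clusters, so these medians cannot separate the cluster mix from a change within cells.

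Of the genes farthest from every other library, the carbonic anhydrase gene Car9 was at 37.5 against 0.534 CPM in cardiomyocytes, a log2 ratio of 6.13 (5.52 to 6.83), beside Espn, which bundles actin (5.51), and the manganese transporter gene Slc30a10 (6.38). The immediate early genes Egr1 (-2.11, -2.22 to -2.0) and Jun (-1.49, -1.55 to -1.43) were lower there, as was Strip2 (-2.16). In endothelial cells the mitochondrial protein gene Ndufa4l2 (5.66, 5.08 to 6.31) and the glucose transporter gene Slc2a3 (4.29, 4.13 to 4.45) were higher, and Ccser1 (-2.80), the receptor gene Lgr5 (-2.71) and Prdm16 (-1.91) lower. Cushion mesenchyme also had higher Slc2a3 (2.67) and lower Clca3a1 (-5.56, -7.44 to -4.20), Sgcz (-3.69) and Strip2 (-3.13). Neural crest mesenchyme had higher Bhlhe40 (7.23, 5.88 to 9.11) and Bhlhe41 (5.82, 4.27 to 8.10), both transcriptional repressors, and Stc2 (6.08, 4.81 to 9.71), and lower Bcl11b (-3.58), Khdrbs2 (-4.62) and Otogl (-3.68).

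The stress genes Ddit4 (5.28, 4.87 to 5.72) and Asns (2.91, 2.63 to 3.20) lay farthest from the wild type in the unfolded protein list in neural crest mesenchyme, and the list medians ran from 0.51 to 1.30 over 3 classes. Regulators of the second heart field, the progenitor pool that lengthens the outflow tract, had medians of 0.29 to 0.66 in 3 classes, with Tdgf1 (3.04, 2.88 to 3.20) and Fgf8 (2.02, 1.77 to 2.28) leading in cardiomyocytes, but -0.55 in endothelial cells. With 20 CPM asked of each member these were 0.24 in cushion mesenchyme (main 0.53) and -0.25 in endothelial cells. The retinoic acid pathway had medians of 0.47 to 0.76 in 3 classes with members of both signs (Aldh1a2 -3.42 and Cyp26b1 3.21 in neural crest mesenchyme), and the median there was 0.03 when a mean of 20 CPM was asked of each member. Haemoglobin genes had medians of -4.50 to -3.38. Erythroid cells were 0.149% of this library and 1.42% of the wild type, and haemoglobin over all cells was at 649.6 and 8951 CPM. Mitochondrially encoded genes had medians of -1.07 to -0.46 (mt-Cytb -1.88 in neural crest mesenchyme) and cholesterol synthesis genes of -0.68 to -0.41. Sarcomere genes were lower by their medians outside cardiomyocytes (-0.72 to -0.25), but Tpm1 (1.15, 1.10 to 1.21), Actc1 (0.52, 0.45 to 0.59) and Myh7 (1.12, 0.92 to 1.31) were higher in neural crest mesenchyme. The summed level of the list there was 2731 CPM, against 2385 in the wild type. At 20 CPM the medians were -0.99 there (main -0.42) and -0.65 in endothelial cells (main -0.25). Ribosomal protein genes had medians of 0.23 to 0.69 in 3 classes, and the cushion one, at 0.23, became 0.07 with finer clusters. Without TMM scaling the median of all genes moved by -0.12 in endothelial cells and -0.18 in neural crest mesenchyme of this library, by -0.12 in endothelial cells of the Pkhd1l1 knockout, and by -0.13 in endothelial cells and -0.10 in neural crest mesenchyme of the Ppef2 knockout, and the ribosomal medians kept their sign.

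**Figure D2:**
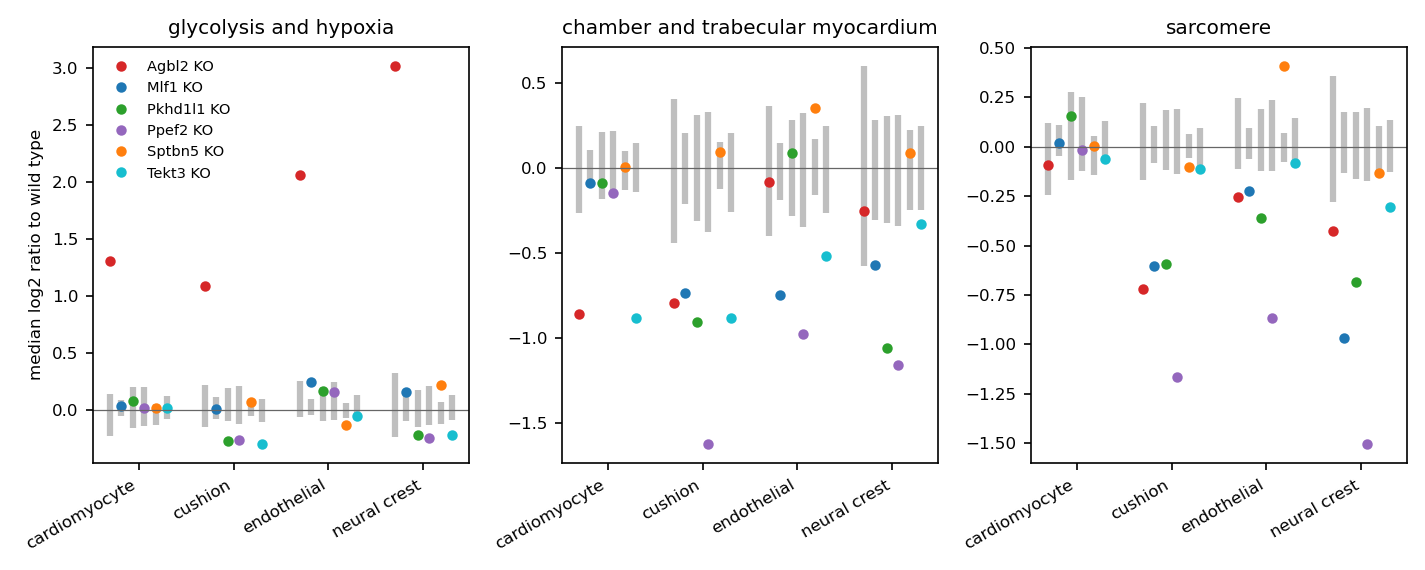
Median log2 ratio to the wild-type library of the glycolysis and hypoxia, chamber and trabecular, and sarcomere lists in 4 cell classes for the 6 knockout libraries, with gray bars for the range of expression-matched random lists. The Agbl2 knockout lay at 1.09 to 3.02 for glycolysis and hypoxia, the Tekt3 knockout at -0.88 for chamber genes in cardiomyocytes, and the Ppef2 knockout at -1.5 for sarcomere genes in neural crest mesenchyme.

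In the Mlf1 knockout library, the list of extracellular matrix genes was lower by its median, though Lum in neural crest mesenchyme and Hapln1 in endothelial cells were higher, and genes of DNA replication were higher. Elastin (Eln) and the matrix protein gene Postn, which cushion and smooth muscle precursors lay down, were lower in cardiomyocytes, cushion mesenchyme and endothelial cells, and Eln was lower in neural crest mesenchyme too. Targets of TGF-beta, which induces much of this matrix, were lower in all 4 classes. Postn and Fn1 belong to both lists, so these lists are not independent. S phase genes were higher in all 4 classes, by small amounts shared by nearly all members.

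Eln was at -1.39 (-1.56 to -1.22) in cardiomyocytes, -2.05 (-2.52 to -1.61) in cushion mesenchyme, -1.82 (-2.01 to -1.63) in endothelial cells and -1.96 (-2.60 to -1.34) in neural crest mesenchyme, and collagen and matrix medians ran from -0.43 to -0.10. Postn was at -2.09 (-2.30 to -1.87) in cardiomyocytes and -0.96 (-1.0 to -0.91) in cushion mesenchyme, where the collagen gene Col1a2 was at -0.96 (-1.06 to -0.86) and Lum at -2.10. Eln, Col1a2 and Iigp1 are among the top 10 genes of the unnamed cluster 14, which held 4.05% of this library's cells and 9.40% of the wild type's, beside cushion mesenchyme at 6.25% and 16.7%. Against the lower values, Lum was at 1.43 (0.77 to 2.14) in neural crest mesenchyme and Hapln1 at 0.43 (0.41 to 0.45) in endothelial cells. Cluster 9, whose cells held a median of 0.366 times their library's median UMIs, was the largest among these cardiomyocytes at 30.6%, against 13.8% of the wild-type ones. The largest in the wild type was cluster 0 (37.4%, and 30.3% here). TGF-beta target medians ran from -0.42 to -0.12, with Tgfbi at -0.85 in cardiomyocytes, Tgfb3 at -0.98 in cushion mesenchyme and the ligand gene Tgfb2 at -1.25 (-1.37 to -1.14) in neural crest mesenchyme. S phase medians ran from 0.16 to 0.24, with 38 of 38 members higher in endothelial cells and 38 of 38 in neural crest mesenchyme, led by Cdc6 (0.73) and Hells (0.57). In cardiomyocytes the histone genes Hist1h1b (0.63) and Hist1h4d (0.85) and Igfbpl1 (0.50) lay above every other library, and Dlg2 (-1.01) below.

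Cushion mesenchyme had higher Cd93 (1.01), Galntl6 (0.91) and Prkcb (0.77) and lower Iigp1 (-2.12, -2.47 to -1.79) and the smooth muscle gene Cnn1 (-0.82). Neural crest mesenchyme had higher Sgcz (2.03), the pharyngeal arch gene Barx1 (1.70, 1.30 to 2.13) and the kinase gene Cdk6 (0.95), and lower Sorcs1 (-2.08, -2.49 to -1.69), Ebf2 (-1.84, -2.14 to -1.54) and Col12a1 (-1.08). Endothelial cells had smaller differences, with Nostrin (0.44), Stpg4 (0.38) and Caprin2 (0.38) higher and Ypel3 (-0.76), Nr6a1os (-0.54) and Ankrd1 lower, though Ankrd1 at -0.87 became 0.25 with finer clusters. Ribosomal protein genes were higher in 3 classes (0.17 to 0.35). Sarcomere genes had medians of -0.97 to -0.23 outside cardiomyocytes. With finer clusters the endothelial value became 0.99 and the cushion one -0.37 (main -0.60). Chamber genes had medians of -0.75 to -0.57 in the same classes, with Myl2 at -1.63 and Nppa at -1.75 in neural crest mesenchyme, but became 0.26 in cushion mesenchyme and 0.09 in endothelial cells when 20 CPM was asked of each member, and -0.14 and 0.54 in the same classes with finer clusters. Haemoglobin medians were -0.49, -2.57 and -1.47 in cardiomyocytes, cushion and neural crest mesenchyme but 0.55 in endothelial cells, which became -1.5 without doublet removal.

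In the Pkhd1l1 knockout library, nuclear genes of oxidative phosphorylation, which power the mitochondrial respiratory chain, and ribosomal protein genes were higher in all 4 classes. The respiratory chain gene Ndufa4 led the first group in each class, followed by Cox5b in neural crest mesenchyme and by Ndufb8 elsewhere. Targets of BMP signalling such as Id1 and Id3 were higher in all 4 classes, past the random lists in 3. In neural crest mesenchyme the branchial arch patterning gene Dlx6 was lower and Col9a1, a cartilage collagen gene, was higher. The adult-type beta globin genes stood out among haemoglobins.

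Oxidative phosphorylation medians ran from 0.27 to 0.45, with 25 of 25 members higher in cardiomyocytes and 24 of 24 in endothelial cells. Cluster 9, with a median of 0.366 times the median UMIs of its cells' own library and no cardiomyocyte marker among its top 10 genes, held 39.2% of these cardiomyocytes and 13.8% of the wild-type ones, and cluster 0 held 24.1% and 37.4%. Ndufa4 was at 0.96 (0.94 to 0.98) in cardiomyocytes, 1.07 (1.04 to 1.10) in cushion mesenchyme, 1.12 (1.08 to 1.15) in endothelial cells and 0.88 (0.82 to 0.94) in neural crest mesenchyme. The ATP synthase gene Atp5g2 lay above every other library in cardiomyocytes (1.27, 1.18 to 1.36), cushion mesenchyme (1.14, 1.0 to 1.27) and endothelial cells (1.20, 1.07 to 1.33), where Impdh2, for guanine nucleotide synthesis, lay below all of them (-0.67, -0.85 and -0.64). Gstp1 (0.94) and Hmgn2 (0.48) were higher and Myh9 (-0.45) and Rgs6 (-0.69) lower in cardiomyocytes, Ftl1 (0.65) higher and Fbxl18 (-0.85) and Mga (-0.38) lower in cushion mesenchyme, and the tight junction gene Cldn5 (1.28, 1.07 to 1.5) higher and Nabp1 (-0.72) and Zfp318 (-0.49) lower in endothelial cells. BMP target medians ran from 0.31 to 0.43 in 3 classes, with Id1 at 0.86 (0.77 to 0.94) and Id3 at 0.82 (0.75 to 0.89) in cardiomyocytes and Msx2 at 1.11 (0.91 to 1.31) in cushion mesenchyme. Ribosomal medians ran from 0.27 to 0.48.

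In neural crest mesenchyme Ebf2 (1.64, 1.47 to 1.81), the natriuretic peptide receptor gene Npr3 (1.72, 1.18 to 2.31) and Col9a1 (1.46, 1.39 to 1.54) were higher, and Dlx6 (-3.09, -3.68 to -2.53), Mycn (-1.28, -1.56 to -0.99) and Pde7b (-1.53, -1.93 to -1.14) were lower than in every other library. Sarcomere genes were lower by their medians outside cardiomyocytes (-0.68 to -0.36), but Tpm1 (0.29, 0.26 to 0.32) and Actc1 (0.20, 0.17 to 0.23) were higher in cushion mesenchyme. Haemoglobin medians ran from 0.76 to 2.52 by class. When 20 CPM was asked of each member they were 0.78 in cardiomyocytes (main 1.48), -1.75 in cushion mesenchyme (main 0.76), 0.60 in endothelial cells (main 1.88) and 0.33 in neural crest mesenchyme (main 2.52). The endothelial one was -0.52 without doublet removal. The members parted, with Hbb-bs at 7.00 (6.29 to 7.81) in cushion mesenchyme, where the embryonic genes Hbb-y (-2.01, -2.11 to -1.91) and Hbb-bh1 (-1.86, -2.05 to -1.68) were lower.

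In the Ppef2 knockout library, transcripts of the contractile apparatus were lower in the cells that do not contract, though Tpm1 and Actc1 in cushion mesenchyme were higher, while in cardiomyocytes some were higher and some lower. The myosin and troponin genes Myl2, Myl3 and Tnni3 were lower in cushion and neural crest mesenchyme and Myl3 and Tnni3 in endothelial cells. Haemoglobin genes were higher in all 4 classes of this library, which also had the most erythroid cells, but in endothelial cells they were lower when no doublets were removed. Spp1, a secreted matrix phosphoprotein gene, was higher and the patterning gene Irx1 lower in neural crest mesenchyme.

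Sarcomere medians were -1.16 in cushion mesenchyme, -0.87 in endothelial cells and -1.5 in neural crest mesenchyme, against -0.02 in cardiomyocytes. There Myl7 (0.53, 0.52 to 0.54) and Tnnc1 (0.52) were higher and Mybpc3 (-0.38, -0.41 to -0.35) and Ttn (-0.33) lower. Tnni3 was at -2.30 (-2.78 to -1.86), -1.56 (-1.91 to -1.23) and -2.48 (-2.97 to -2.01) in the other 3 classes, in the same order, Myl3 at -2.04, -1.53 and -2.17, and Acta1 at -1.66 in endothelial cells. Against this, Tpm1 was at 0.60 (0.57 to 0.63) and Actc1 at 0.46 (0.43 to 0.49) in cushion mesenchyme, where they made up 81.3% of the sarcomere counts, while Actc1 was at -0.96 (-1.01 to -0.90) in endothelial cells and -1.36 (-1.45 to -1.27) in neural crest mesenchyme. Myl7 (-1.64, -1.75 to -1.53) and the calcium pump regulator gene Pln (-2.25, -2.62 to -1.89) in cushion mesenchyme and Tnnt2 (-2.03, -2.25 to -1.81) in neural crest mesenchyme were lower than in every other library. Chamber genes had medians of -1.62 to -0.97 in the same 3 classes, with Nppa at -2.66 in endothelial cells, but with 20 CPM asked of each member they became 0.11 in cushion mesenchyme, where Hand1 was at 1.87, 0.15 in endothelial cells and -0.52 in neural crest mesenchyme (main -1.16). With the strict cell filter the endothelial median was -0.43 (main -0.97), and with finer clusters the cushion one was -0.74 (main -1.62).

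In cardiomyocytes the phosphatase subunit gene Ppp2r2b (1.53, 1.35 to 1.71), the retinoic acid binding protein gene Crabp2 (2.57, 2.33 to 2.83) and Lgi2 (0.41) were higher and Thsd7a (-0.85), Pak3 (-0.75) and Mir6236 (-1.25) lower than in every other library. 35.5% of these cardiomyocytes lay in cluster 24, which held 1.23% of the wild-type ones and whose cells were shallow, with a median of 0.306 times the median UMIs of their own library. Cushion mesenchyme had higher Hsd11b2 (2.70, 2.45 to 2.95), Rerg (1.28) and Glipr1 (1.0), and the immediate early gene Junb was lower in cushion mesenchyme (-1.09) and endothelial cells (-1.23, -1.40 to -1.07). Endothelial cells had higher S100a6 (1.09), C1galt1c1 (0.72) and Rfk (0.53) and lower Amy1 (-0.80) and Pde4b (-0.93). Neural crest mesenchyme had higher Spp1 (3.64, 2.82 to 4.60), the imprinted gene Dlk1 (0.75) and Dlgap1 (0.99) and lower Irx1 (-3.71, -4.18 to -3.27) and the Hedgehog target Foxf2 (-1.55, -1.91 to -1.19). Haemoglobin medians ran from 0.98 to 2.06, led by the embryonic genes Hba-x (2.29 in cardiomyocytes) and Hbb-bh1 (2.23), and the endothelial median became -0.16 without doublet removal. Oxidative phosphorylation genes (0.27 to 0.43, led by Ndufa1 at 0.59 in cardiomyocytes) and ribosomal protein genes (0.35 to 0.52, led by Rpl36al at 1.32) were higher in all 4 classes. The sex-linked list was higher (0.62 to 1.09), with the Y-linked Eif2s3y at 1.17 (1.04 to 1.31) and Xist at -1.78 (-1.87 to -1.69) in cushion mesenchyme.

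In the Sptbn5 knockout library, genes of the Lin28 and let-7 pathway, which are high in young embryonic tissue and decline as it matures, were lower in all 4 classes. Trim71 and Arid3a were lower in each class, and Lin28a in both mesenchymes. Collagen and matrix genes were higher in 3 classes, and Postn and Fbln2, which are markers of cushion mesenchyme, were higher in cardiomyocytes, whose largest cluster was not the one of the wild type. Cntn4, a neural adhesion molecule gene, and Fbln5, for elastic fibres, were higher in cushion mesenchyme, and the Wnt antagonist gene Dkk1 was lower in neural crest mesenchyme.

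The developmental timing medians ran from -0.49 to -0.18, with 0 of 7 members higher in cardiomyocytes and 0 of 7 in endothelial cells. The neural crest median was the lowest, at -0.49, and became -0.24 with 20 CPM asked of each member. Trim71 was at -0.74 (-0.90 to -0.57) in cardiomyocytes, -0.62 (-0.83 to -0.41) in cushion mesenchyme, -1.16 (-1.57 to -0.76) in endothelial cells and -0.80 (-1.14 to -0.46) in neural crest mesenchyme, and Lin28a at -1.75 (-2.64 to -0.92) in cushion and -2.03 (-3.04 to -1.14) in neural crest mesenchyme. Collagen and matrix medians ran from 0.11 to 0.44 in 3 classes, and that of cardiomyocytes, at 0.44, became 0.20 at 20 CPM. Fbln2 (1.88, 1.69 to 2.06), Postn (1.58, 1.46 to 1.71) and Papss2 (1.61, 1.43 to 1.80) were higher in cardiomyocytes than in every other library, while Col8a1 (-1.05, -1.22 to -0.89), the ephrin receptor gene Epha6 (-1.03) and Igdcc3 (-0.90) were lower. Fbln2, Postn, Col3a1 (1.70, 1.62 to 1.77) and Hapln1 (1.41, 1.33 to 1.5) are among the markers that named cushion mesenchyme. Cluster 9 held 50.4% of these cardiomyocytes and 13.8% of the wild-type ones.

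Cushion mesenchyme had higher Cntn4 (2.84, 2.49 to 3.22), Kcnip4 (2.44, 2.14 to 2.75) and Fbln5 (1.49, 1.34 to 1.65), and lower Krt8 (-0.85), Dlk1 (-0.82) and Hand1 (-0.79). Cntn4 is also a top gene of the unnamed cluster 16 of the finer clusters, which held 6.31% of this library's cells and 4.08% of the wild type's, but only 0.623% and 1.08% of the cushion mesenchyme. Endothelial cells, 36.0% of them in cluster 3, their largest cluster (cluster 20 in the wild type), had higher Mgp (1.31, 1.12 to 1.5), which restrains calcification, Clca3a1 (1.14) and Fam155a (1.08) and lower Igfbp3 (-0.61), Adamts19 (-0.53) and the gap junction gene Gja5 (-0.74). Neural crest mesenchyme had higher Ano3 (2.84, 2.20 to 3.53), Sostdc1 (2.65, 2.06 to 3.30) and Angptl1 (1.91) and lower Dkk1 (-2.51, -3.06 to -1.99), Igdcc3 (-2.35, -2.56 to -2.14) and Adam12 (-2.12, -2.53 to -1.73). Cholesterol synthesis genes were higher in 3 classes (0.14 to 0.20), with Insig1 at 0.91 (0.76 to 1.05) in cardiomyocytes and Msmo1 at 0.63 (0.48 to 0.78) in cushion mesenchyme. Oxidative phosphorylation medians were small (0.05 to 0.11), led by Ndufb8 (0.37) and Uqcrc1 (0.30) in cardiomyocytes. The sex-linked list was lower in 3 classes (-1.03 to -0.28), with Kdm5d at -1.08 (-1.29 to -0.87) and Uty at -1.07 (-1.21 to -0.95) in cardiomyocytes.

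In the Tekt3 knockout library, cardiomyocytes had less of the transcripts that mark the working myocardium of the heart chambers. The connexin genes Gja1 and Gja5, the peptide hormone gene Nppa and the trabecular growth factor gene Bmp10 were all lower. Targets of BMP signalling were higher in all 4 classes, Notch pathway genes and targets of FGF and canonical Wnt signalling in 3, and regulators of the second heart field, led by Tdgf1 and Isl1 in cardiomyocytes, were higher in 3, though in cushion mesenchyme not with finer clusters. The immediate early genes Fos and Fosb, which respond to tissue dissociation, were higher as well. The second heart field and retinoic acid lists were higher in 3 classes both here and in the Agbl2 knockout, which shares this library's date. The chamber gene Myl2 was low in cardiomyocytes of both (2855 and 2556 CPM, wild type 5221), but Nppa here only. For what both libraries share, date and genotype cannot be told apart.

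Chamber and trabecular genes had a median of -0.88 in cardiomyocytes, with 2 of 12 members higher. Gja1 was at -2.27 (-2.41 to -2.13), Bmp10 at -2.16 (-2.43 to -1.91), Gja5 at -2.15 (-2.54 to -1.77), Cited1 at -1.92 (-2.01 to -1.84) and Nppa at -1.59 (-1.68 to -1.5), with Nppa at 43.4 against 131 CPM and 121 to 444 CPM in the other libraries. 47.1% of these cardiomyocytes lay in cluster 13, which held 28.7% of the wild-type ones. The list was also lower in cushion mesenchyme (-0.88) and endothelial cells (-0.52), but with 20 CPM asked of each member these became 0.33 and 0.12. With finer clusters the cushion median was -0.33, and with the strict cell filter the endothelial one was -0.21. Second heart field medians ran from 0.21 to 0.41 in 3 classes, with Tdgf1 at 1.87 (1.70 to 2.05) and Isl1 at 1.19 (1.12 to 1.26) in cardiomyocytes and Eya1 at 1.89 (1.49 to 2.32) in cushion mesenchyme, where the median became -0.02 with finer clusters and -0.08 at 20 CPM. In neural crest mesenchyme 0.26 became 0.05 with finer clusters.

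BMP target medians were 0.97 in cardiomyocytes, 0.32 in cushion mesenchyme, 0.56 in endothelial cells and 0.48 in neural crest mesenchyme, with 10 of 10 members higher in cardiomyocytes, led by Msx2 (1.38, 1.26 to 1.5) and Id1 (1.32, 1.24 to 1.41). FGF feedback target medians ran from 0.18 to 0.55 (Dusp6 1.02 in cushion mesenchyme), Notch pathway medians from 0.35 to 0.68 (Hey1 0.93 in endothelial cells, but Hey2 -0.94 in cardiomyocytes) and canonical Wnt medians from 0.37 to 0.46 (Dkk1 0.96 in endothelial cells). At 20 CPM the Notch median was 0.17 in endothelial cells (main 0.35) and 0.42 in neural crest mesenchyme (main 0.68, and 0.27 with finer clusters), and in cushion mesenchyme it was 0.25 (main 0.01). The Wnt median was 0.06 in neural crest mesenchyme (main 0.37) and 0.51 in cushion mesenchyme (main 0.15). The retinoic acid pathway ran from 0.37 to 0.68, with Crabp2 at 1.84 (1.58 to 2.11) in cardiomyocytes, where the median became 0.09 at 20 CPM. Dissociation genes had medians of 0.15 to 0.74, led by Fosb (2.46, 2.30 to 2.62) and Fos (1.26, 1.22 to 1.30) in cardiomyocytes, beside Atf3 (0.82), Btg2 (0.94) and the nuclear protein gene Zfp503 (1.08). Their neural crest median of 0.47 became 0.17 at 20 CPM, 0.15 with finer clusters and 0.27 without doublet removal. Cholesterol synthesis medians ran from 0.21 to 0.39 (Insig1 1.13 in cardiomyocytes) and G2 and M phase medians from -0.22 to -0.06 (Mki67 -0.50 in cushion mesenchyme, where the median of -0.22 became -0.06 with finer clusters).

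In endothelial cells Dpy19l2 (1.74, 1.49 to 2.01), Cnnm2 (0.87) and the matrix-signalling gene Cyr61 (1.45, 1.37 to 1.53) were higher, and the transcription factor gene Irx5 (-2.30, -2.47 to -2.13), Pkdcc (-1.88) and Frem1 (-1.86, -2.01 to -1.70) lower than in every other library. Cluster 3, of which Irx5 is a leading gene, held 6.17% of these endothelial cells and 33.2% of the wild-type ones, and cluster 20 held 71.2% and 43.9%. Cushion mesenchyme had higher Gadd45g (1.14), Itgb6 (0.86) and Sgk1 (0.85) and lower Lsm3 (-0.55), the ferritin gene Ftl1 (-0.61) and D5Ertd579e (-0.55). Neural crest mesenchyme had higher Agbl3, a paralogue of Agbl2 (1.08, 0.71 to 1.46), Cspg5 (0.73) and Fos (1.14) and lower Akap10 (-0.69), BC065397 (-0.77) and Ftl1 (-0.56). The sex-linked list was higher in all 4 classes (0.40 to 0.82), with Xist at -1.68 (-1.75 to -1.61) in cushion mesenchyme and Ddx3y at 1.01 (0.91 to 1.11).

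**Figure D3:**
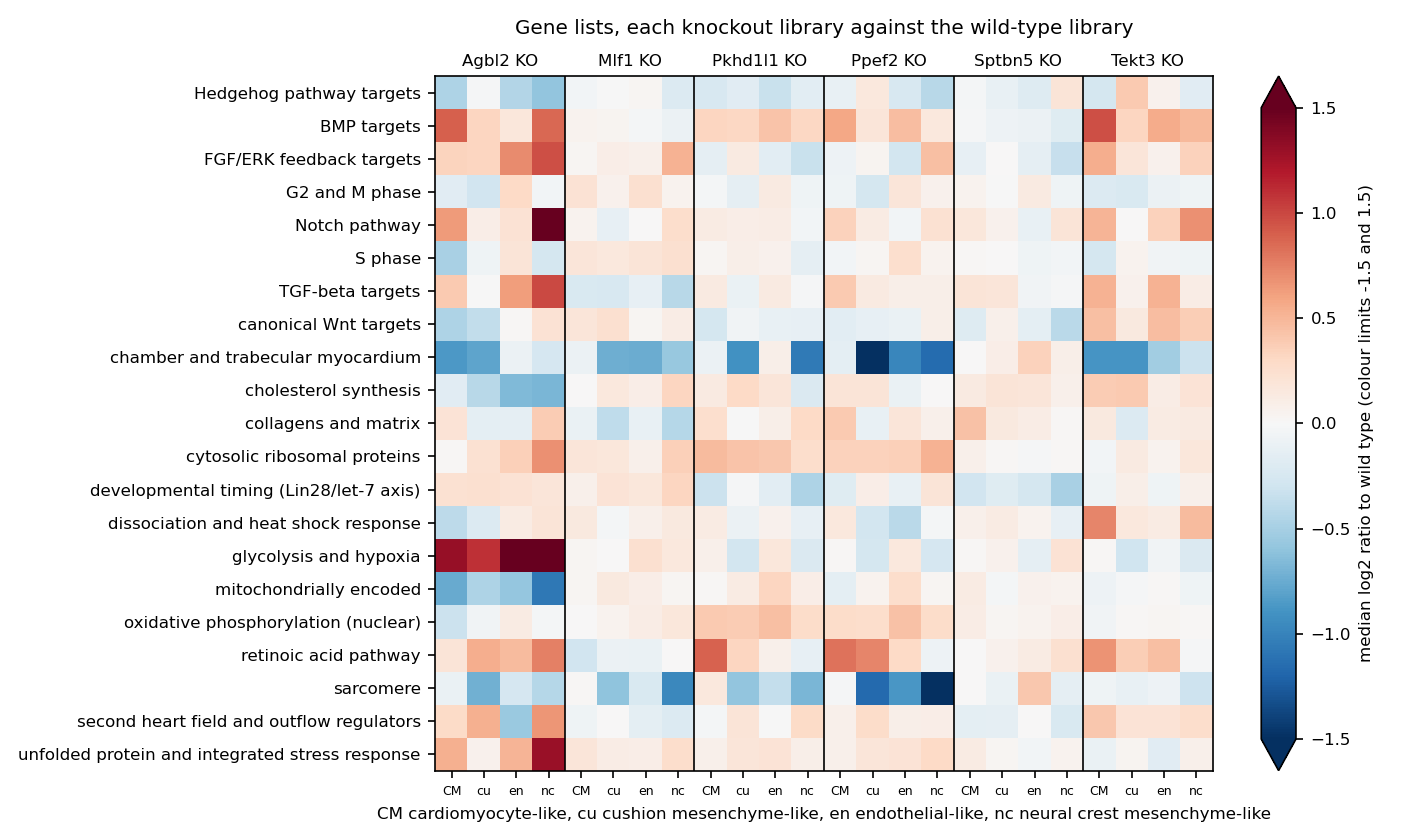
Median log2 ratio to the wild-type library of gene lists in 4 cell classes of the 6 knockout libraries, with colours limited at -1.5 and 1.5. The highest median shown was 3.02, for glycolysis and hypoxia genes in neural crest mesenchyme of the Agbl2 knockout.

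How far single libraries part from each other bears on all of these values. Of the genes measured in a class, between 16.5% (Tekt3 knockout, neural crest mesenchyme) and 63.4% (Agbl2 knockout, neural crest mesenchyme) placed a knockout library outside the range of the other 6, where chance gives 28.6%. The gene lists fell outside the central range of random lists in 21.6% to 60.5% of cases per knockout and class. All 6 comparisons share the 1 wild-type library, so a chance feature of that library appears in each of them.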

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

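The test of the cardiomyocyte clusters in the Tekt3 knockout and that of sarcomere levels across the libraries were chosen before their results were seen, and the other tests here only after. A knockout library was singled out where its gap to the nearest of the other 5, over the range of the 6, passed Dixon's 95% critical value. This held in 22 of 140 groups, 19 of them for the Agbl2 knockout, 2 for the Ppef2 and 1 for the Tekt3 knockout, where chance marks about 5% of groups. The groups share the wild-type library and overlapping lists, so they are not independent.

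Glycolysis and hypoxia genes in the Agbl2 knockout stood apart from the other knockouts with medians of 1.31 (cardiomyocytes), 1.09 (cushion mesenchyme), 2.06 (endothelial cells) and 3.02 (neural crest mesenchyme), against next highest medians of 0.08, 0.07, 0.24 and 0.22. A batch shared by libraries of the same date is argued against by the Tekt3 knockout of that date, whose highest median over the 4 classes was 0.0123. RNA free in the suspension would add about the same CPM to each class, and between neural crest mesenchyme and cardiomyocytes it nearly did (median ratio of the differences 1.45, 95% bootstrap interval over members 0.858 to 2.42). Between cushion and neural crest mesenchyme the ratio was 0.200 (0.164 to 0.215), which free RNA does not give, so it is argued against as the whole cause. Oxygen shortage or handling of this library and the loss of Agbl2 cannot be told apart, because the genotype has 1 library, whose lowest median was 1.09, and either may be the source.

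Chamber and trabecular genes in cardiomyocytes of the Tekt3 knockout had a median of -0.88 and were weighed for that size. Another mix of cardiomyocyte clusters was tested within cluster 13, where the median was -0.19, with -1.03, -0.36 and -0.24 in clusters 9, 0 and 12. Since 9 of the 13 members helped to define the clusters, this decides nothing and a different mix stays open. Less chamber tissue in the dissected piece was held to the share of endothelial cells in cluster 3, which was 6.17% against 17% to 36.0% in the other 6 libraries. Since clusters 20 and 25 have the endocardial markers Nfatc1 and Npr3 up as well, this share does not count endocardial cells, so it decides nothing and the dissection stays open. An effect of the genotype stays open as well, since there is 1 library. The date shared with the Agbl2 knockout, whose Myl2 was low too, was not tested as a source.

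Sarcomere genes in cushion and neural crest mesenchyme of the Ppef2 knockout had medians of -1.16 and -1.5. Were cardiomyocyte RNA free in the suspension the source, the level in cushion mesenchyme was predicted to follow that over all cells, but across the 7 libraries r was -0.67 (exact permutation p = 0.0889, adjusted p = 0.160 over 9 correlations), rho was -0.714 (p = 0.0881, adjusted p = 0.375) and r was -0.641 without the Mlf1 and Ppef2 knockouts, the libraries farthest out. This met the bound written beforehand against free RNA. That bound was judged wrong afterwards, since Tpm1 and Actc1, 56.6% to 81.3% of the cushion sum, were taken as made by mesenchyme. This was not tested (Actc1 in the Ppef2 knockout was at 1005 CPM in cushion mesenchyme but 167 in neural crest and endothelial cells). For the other members r was 0.39 (exact permutation p = 0.390, adjusted p = 0.501), rho was 0.250 (p = 0.595, adjusted p = 0.669) and r was -0.383 without the same 2 libraries. Over all 7 this lies between the bounds for and against free RNA, so it decides nothing. By member, the level in neural crest mesenchyme was 0.846 times that in endothelial cells of the Ppef2 knockout (median of 18 members) and 1.29 times in the wild type, where cardiomyocytes held 35.1 times the endothelial level, as free cardiomyocyte RNA would give, which stays open as the source. An effect of the genotype confined to mesenchyme is argued against by the endothelial median of -0.87.

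Of the other values set apart, erythroid cells were 4.27% of the Ppef2 knockout library (next 1.21%), and Mlf1 was at 12.7 CPM over all cells of the Agbl2 knockout (next 22.8). Mitochondrially encoded genes in the Agbl2 knockout had medians of -0.76 (cardiomyocytes), -0.46 (cushion mesenchyme), -0.58 (endothelial cells) and -1.07 (neural crest mesenchyme). Its cholesterol synthesis genes were at -0.41 (cushion mesenchyme) and -0.66 (endothelial cells), and its haemoglobins at -3.38 (endothelial cells). Genes of tubulin glutamylation and tyrosination, a modification that Agbl2 trims, were at -0.35 (cardiomyocytes) and -0.24 (endothelial cells) in the same knockout. Ciliary genes of its cushion mesenchyme were higher, at 0.21 for the transition zone (next 0.07) and 0.12 for intraflagellar transport (next 0.01). Unfolded protein response genes were at 1.30 and TGF-beta targets at 0.99 in its neural crest mesenchyme, and FGF feedback targets at 0.70 in its endothelial cells. In endothelial cells, canonical Wnt targets of the Tekt3 knockout were at 0.46 (next 0.03) and dissociation and heat shock genes of the Ppef2 knockout at -0.40 (next 0.05).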

How the results depend on the processing

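The genes and lists called with the date code as a block, the lists called with a knockout library left out and the hypoxia list within single clusters were chosen only after the data were seen, and the other alternatives before. The count of 0 genes for the wild type against 6 knockouts held in all 68 combinations of class and alternative, DESeq2 and leaving out each knockout included. The lists called in cardiomyocytes, cushion mesenchyme, endothelial cells and neural crest mesenchyme (10, 8, 5 and 5) numbered 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 1 with fry, and 11 to 17, 7 to 10, 4 to 8 and 5 to 9 with each knockout library left out in turn. With the date code as a block in the edgeR fit, which leaves 2 residual degrees of freedom and compares the wild type with the 2 knockouts of its date, they numbered 7, 8, 3 and 6. An estimated correlation takes in how members vary together between libraries, which the preset leaves out. Of 1920 list medians under an alternative, 1811 moved by less than the spread of random lists, 94 moved by more and 15 changed sign. Named genes were held to their counting intervals and shares to the counting error of the difference. For named genes the counts were 540, 35 and 1 of 576, and for shares 169, 74 and 3 of 246. Named genes that moved lay nearer 0 in 14 cases and farther in 8 with finer clusters, 4 and 4 without TMM, 3 and 0 without doublet removal and 1 and 1 with the strict filter. Of the lists on cilia and their signalling that are not described for a knockout, 2 medians moved nearer 0 and 7 farther at 20 CPM, and 1 farther with finer clusters. The other values that moved and all that were counted as changed in sign follow by setting, with shares in percentage points and lists as median log2 ratios, each knockout against wild type. The cause was not tested, except that a higher detection limit takes in fewer members and that finer clusters or marker scores reassign cells. No label pairs the libraries, so the date code was the only block available.

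With finer clusters (Leiden resolution 2) values were as follows. Cardiomyocyte shares differed by 2.36 (Agbl2), 11 (Mlf1), -3.34 (Pkhd1l1) and -9.02 (Ppef2). Cushion shares differed by -8.54 (Agbl2), -6.66 (Mlf1), -3.24 (Pkhd1l1), -6.92 (Ppef2) and -1.51 (Tekt3). Endothelial shares differed by 6.13 (Mlf1). Neural crest shares differed by 11.3 (Agbl2), 6.86 (Ppef2) and 1.72 (Tekt3). Epithelial shares differed by 1.46 (Pkhd1l1) and 3.40 (Ppef2). Erythroid shares differed by 4.06 (Ppef2). Haemoglobins were at -5.32 (Agbl2), -0.89 (Mlf1), 1.16 (Pkhd1l1) and 1.51 (Ppef2) in cardiomyocytes, -2.37 (Mlf1) and 1.27 (Pkhd1l1) in cushion mesenchyme, 0.84 (Mlf1) and 2.23 (Pkhd1l1) in endothelial cells and 1.26 (Ppef2) in neural crest mesenchyme. Ribosomal protein genes were at 0.0719 (Agbl2) and 0.14 (Mlf1) in cushion mesenchyme. Glycolysis and hypoxia genes were at 0.90 (Agbl2) in cushion mesenchyme. Second heart field genes were at 0.26 (Agbl2) and -0.0174 (Tekt3) in cushion mesenchyme and 0.0529 (Tekt3) in neural crest mesenchyme. S phase genes were at 0.23 (Mlf1) in cushion mesenchyme and 0.34 (Mlf1) in neural crest mesenchyme. TGF-beta targets were at -0.38 (Mlf1) in cushion mesenchyme. Chamber genes were at -0.14 (Mlf1), -0.74 (Ppef2) and -0.33 (Tekt3) in cushion mesenchyme, 0.54 (Mlf1) in endothelial cells and -0.98 (Mlf1) and -0.72 (Tekt3) in neural crest mesenchyme. Sarcomere genes were at -0.37 (Mlf1) and -0.43 (Pkhd1l1) in cushion mesenchyme, -0.56 (Agbl2) and 0.99 (Mlf1) in endothelial cells and -1.20 (Ppef2) in neural crest mesenchyme. G2 and M phase genes were at -0.0625 (Tekt3) in cushion mesenchyme. Collagens and matrix were at -0.61 (Mlf1) in neural crest mesenchyme. Notch genes were at 0.27 (Tekt3) in neural crest mesenchyme. Dissociation genes were at 0.15 (Tekt3) in neural crest mesenchyme. Ankrd1 was at 0.25 (Mlf1) in endothelial cells.

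With each cell in the class of its highest marker score, shares alone were recomputed. Cardiomyocyte differences were 5.92 (Agbl2), 12 (Mlf1), -8.10 (Pkhd1l1), -13.7 (Ppef2), -3.08 (Sptbn5) and -8.74 (Tekt3). Cushion differences were -11.9 (Agbl2), -2.92 (Pkhd1l1), -8.55 (Ppef2), 4.66 (Sptbn5) and -1.65 (Tekt3). Endothelial differences were 0.437 (Agbl2), 3.96 (Mlf1) and -0.597 (Sptbn5). Neural crest differences were 2.26 (Mlf1), 2.27 (Pkhd1l1), 5.80 (Ppef2), -1.08 (Sptbn5) and 4.21 (Tekt3). Epicardial differences were -5.67 (Agbl2), -2.76 (Mlf1), -3.99 (Pkhd1l1), -2.0 (Ppef2) and -3.39 (Tekt3). Epithelial differences were 3.91 (Agbl2), 1.83 (Pkhd1l1), 3.36 (Ppef2) and 2.70 (Tekt3). Erythroid differences were -3.76 (Agbl2), -1.56 (Mlf1), -0.568 (Pkhd1l1), 15.4 (Ppef2) and -0.550 (Tekt3).

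With the strict cell filter, the following moved. Cardiomyocyte shares differed by 13.5 (Agbl2), -3.80 (Pkhd1l1), -12.7 (Ppef2) and 1.30 (Sptbn5). Cushion shares differed by -15.5 (Agbl2), -13.0 (Mlf1), -6.46 (Pkhd1l1), -11.2 (Ppef2) and 1.14 (Tekt3). Endothelial shares differed by -2.31 (Pkhd1l1) and -3.57 (Sptbn5). Neural crest shares differed by 13.6 (Agbl2), 1.38 (Mlf1), 5.70 (Pkhd1l1), 4.79 (Ppef2) and 3.85 (Tekt3). Epicardial shares differed by -5.89 (Agbl2), -3.83 (Pkhd1l1) and -3.41 (Tekt3). Epithelial shares differed by 3.36 (Agbl2), 2.36 (Mlf1), 0.174 (Pkhd1l1) and 4.46 (Ppef2). Erythroid shares differed by -0.468 (Agbl2), -0.108 (Mlf1), -0.371 (Pkhd1l1), 4.41 (Ppef2) and -0.608 (Tekt3). Haemoglobins were at -5.28 (Agbl2) and -0.84 (Mlf1) in cardiomyocytes. Chamber genes were at -0.36 (Ppef2) in cardiomyocytes and -0.52 (Mlf1), -0.43 (Ppef2) and -0.21 (Tekt3) in endothelial cells.

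With a detection limit of 20 CPM, list medians moved as follows. Haemoglobins were at 0.78 (Pkhd1l1) in cardiomyocytes, -1.75 (Pkhd1l1) in cushion mesenchyme, 0.70 (Mlf1) and 0.60 (Pkhd1l1) in endothelial cells and 0.33 (Pkhd1l1) in neural crest mesenchyme. Collagens and matrix were at 0.20 (Sptbn5) in cardiomyocytes and -0.27 (Mlf1) in cushion mesenchyme. Retinoic acid genes were at 0.0872 (Tekt3) in cardiomyocytes and 0.0343 (Agbl2) in neural crest mesenchyme. Glycolysis and hypoxia genes were at 0.89 (Agbl2) in cushion mesenchyme. Second heart field genes were at 0.24 (Agbl2) and -0.0810 (Tekt3) in cushion mesenchyme and -0.25 (Agbl2) in endothelial cells. Chamber genes were at 0.26 (Mlf1), 0.11 (Ppef2) and 0.33 (Tekt3) in cushion mesenchyme, 0.0890 (Mlf1), 0.15 (Ppef2) and 0.12 (Tekt3) in endothelial cells and -0.52 (Ppef2) in neural crest mesenchyme. Sarcomere genes were at -0.72 (Mlf1) in cushion mesenchyme, -0.65 (Agbl2) and -0.46 (Mlf1) in endothelial cells and -0.99 (Agbl2), -1.22 (Mlf1) and -1.72 (Ppef2) in neural crest mesenchyme. Tubulin glutamylation genes were at 0.0753 (Ppef2) in cushion mesenchyme. Notch genes were at 0.25 (Tekt3) in cushion mesenchyme, 0.17 (Tekt3) in endothelial cells and 0.42 (Tekt3) in neural crest mesenchyme. Wnt targets were at 0.51 (Tekt3) in cushion mesenchyme and 0.0607 (Tekt3) in neural crest mesenchyme. FGF feedback targets were at 0.27 (Tekt3) in endothelial cells. Hedgehog targets were at 0.51 (Tekt3) in endothelial cells. Developmental timing genes were at -0.24 (Sptbn5) in neural crest mesenchyme. Dissociation genes were at 0.17 (Tekt3) in neural crest mesenchyme.

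Without doublet removal, these moved. Haemoglobins were at -0.77 (Mlf1) in cardiomyocytes, -2.90 (Mlf1) and 1.29 (Pkhd1l1) in cushion mesenchyme, -5.46 (Agbl2), -1.5 (Mlf1), -0.52 (Pkhd1l1) and -0.16 (Ppef2) in endothelial cells and 1.31 (Ppef2) in neural crest mesenchyme. Chamber genes were at -1.22 (Ppef2) in cushion mesenchyme. Sarcomere genes were at -0.59 (Ppef2) in endothelial cells and -0.50 (Pkhd1l1) and -1.26 (Ppef2) in neural crest mesenchyme. Dissociation genes were at 0.27 (Tekt3) in neural crest mesenchyme. Without TMM, only ribosomal medians moved, keeping their sign. They were at 0.24 (Agbl2), 0.0485 (Mlf1), 0.28 (Pkhd1l1) and 0.23 (Ppef2) in endothelial cells and 0.51 (Agbl2), 0.29 (Mlf1) and 0.41 (Ppef2) in neural crest mesenchyme. The hypoxia median of the Agbl2 knockout was 0.57, 0.41 and 0.34 within cardiomyocyte clusters 0, 12 and 13 and 1.84 within endothelial cluster 20. It did not count as moved within endothelial cluster 3. Since these genes were not kept out of the clustering, this does not separate the cluster mix from a change within cells. Depth limits the genes with few counts, for which the counting intervals are wide.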

Other observations

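The fits of single libraries, the comparison of globin genes and the counts of sex-linked transcripts per cell here were chosen only after the data were seen, while the list of anterior Hox genes was fixed before. Set alone against the other 6 libraries in edgeR, the Agbl2 knockout gave 2015 genes in cardiomyocytes (1497 higher, 518 lower), 100 in cushion mesenchyme (83 and 17), 548 in endothelial cells (428 and 120) and 3340 in neural crest mesenchyme (1813 and 1527). In such a fit the lone library has no spread of its own and is assumed to vary like the other 6, which differ in genotype, so the calls compare libraries and not genotypes. The same fits gave 0 genes in each class for the wild type and the Mlf1, Ppef2 and Tekt3 knockouts. There the Agbl2 knockout library is among the other 6, so the counts are not set against the same spread. With the same assumption, Hbb-bs in the Pkhd1l1 knockout had log2 fold changes of 6.84 (cushion mesenchyme), 6.92 (endothelial cells) and 8.79 (neural crest mesenchyme). Cntn4 in cushion mesenchyme of the Sptbn5 knockout was at 3.54.

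Hbb-bs, an adult-type beta globin gene, was at 264 CPM over all cells of the Pkhd1l1 knockout (36232 counts), 13.1 in the wild type and 2.17 to 57.2 in the other 5 knockouts. Counts of the later alpha globin genes over those of embryonic Hba-x were 1.01 in the Pkhd1l1 knockout, 0.634 in the wild type and 0.536 to 0.809 in the others. All haemoglobin genes made up 3.70% of the UMIs in the Ppef2 knockout, 0.895% in the wild type and 0.0650% in the Agbl2 knockout. Haemoglobin over all cells and in the 4 classes gave r of 0.80 to 0.92 over the 7 libraries. Without the Agbl2 and Ppef2 knockouts r was -0.83 to 0.59. Free blood RNA thus stays open as a source.

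Among cells with at least 5000 UMIs, 40.0% of the wild-type library had Y-linked transcripts without Xist and 45.5% had Xist alone. The shares were 70.2% and 14.9% in the Ppef2, 66.0% and 18.9% in the Tekt3, 23.0% and 60.8% in the Sptbn5, 28.9% and 49.4% in the Agbl2, 39.6% and 41.0% in the Mlf1, and 42.2% and 38.0% in the Pkhd1l1 knockout. Cells with both made up 6.96% (Tekt3 knockout) to 18.5% (Agbl2 knockout). No free RNA was taken off, so these are shares by the transcripts found and not by sex.

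Anterior Hox genes, which set position along the body axis, had a median of -0.81 in neural crest mesenchyme of the Pkhd1l1 knockout. Hoxb5 at -4.29 (-5.80 to -3.06) and Hoxb4 at -2.48 (-2.84 to -2.12) were chosen after their values were seen. So was the natriuretic peptide gene Nppb, at 4.93 (4.67 to 5.21) in cardiomyocytes of the Agbl2 knockout.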
